A study of Mus musculus with 6 samples.

How the data were processed

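Chromatin accessibility was measured by single-nucleus ATAC-seq, in which a transposase cuts and tags open chromatin in single nuclei, in pancreatic islets of NOD mice, a strain that develops autoimmune diabetes. There were 3 libraries of NOD mice (WT) and 3 of NOD mice lacking Tet2 (Tet2KO), an enzyme that oxidises 5-methylcytosine in DNA. Per the labels' protocols, islets of 4 to 6 mice per genotype were pooled for a library, 2 to 3 pools were made, and the knockout allele came from a B6 background and was backcrossed to NOD for over 14 generations. The labels give 10 to 13 weeks, in one place as age and in another as weeks after BTM, an abbreviation not spelled out. They also name bone marrow donors without tying them to the islet libraries, so it stays open whether the islet mice had received marrow. They give lysis times of 3 min for 2 libraries and 5 min for 4, by core facility numbers that could not be tied to the libraries used here. The set number in the sample titles was used as the replicate number.

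Per the labels' protocols, up to 12000 nuclei were loaded per lane, with 6000 nuclei and 50000 read pairs per nucleus targeted. Reads were demultiplexed with bcl2fastq 2.20.0.422 and processed with Cell Ranger ATAC 2.1.0 against the 10x mm10 reference, which is built on GRCm38. Signac 1.7.0 is listed in the submitters' processing notes with no step given. The labels name no step for doublets, and none were removed here, so the nucleus counts include any that passed the authors' calling. The deposited values used here are of 2 kinds, text lists of the barcodes called as nuclei and text lists of peak positions. Neither holds a score, and the authors' number of cut sites per peak was not used here. Peak positions differ between libraries, so the authors called peaks separately in each library, and any shift of reads for the transposase offset was part of their pipeline. A peak is therefore a yes or no call per library, and the read depth behind each call is unknown. The median peak width lay between 875 and 878 bp in every library, so a longer covered length means more peaks, not broader ones.

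Peaks on chromosomes 1 to 19, X and Y were used, and between 45 and 57 peaks per library on other scaffolds were left out. In 3 libraries 1 line of the peak list was empty. The gap around each such line was masked in all 6 libraries, which removed at most 3 peaks from a library. Gene positions came from GENCODE vM21 on GRCm38, and all peak ends lay within the chromosome lengths of that build. Of the annotation, 21884 protein-coding genes with a unique symbol were used. Coordinates are 1-based.

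For each gene, the bases under peaks in the gene body plus 2 kb upstream were summed, and libraries were scaled to the same total covered length. Genes with a mean of 500 bp or more (17310 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(covered bp + 500), with a trended and robust prior and Benjamini-Hochberg adjustment at 0.05. The pseudocount makes a log2 difference understate the change of genes with few peaks. Windows of 100 kb were tested in the same way (21157 windows). On data simulated from the gene table with 200 changed genes, the gene test recovered 57% of changes of 1 and 9% of changes of 0.5 on the log2 scale, with 4 false calls, and it made 0 calls when nothing was changed. The window test recovered 60% and 7%, with 3 false calls. The simulation drew each peak call independently, with no effect shared across a library. Changes were planted only in genes or windows averaging 4 or more peak widths. These rates may therefore not hold for genes with few peaks or where a library shifts as a whole.

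Gene lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted over 18 lists. The lists cover beta cell identity, alpha cells, delta and PP cells, acinar, ductal, endothelial and mesenchymal cells, T cells, T cell effector and checkpoint genes, B cells, macrophages and dendritic cells, ER stress and the unfolded protein response, cell death, interferon response, antigen presentation, inflammatory signalling and chemokines, DNA methylation machinery and housekeeping genes. They were written before the data were examined, as were the tests and most alternatives. With no values per nucleus, lists describe genes in a whole library and not cell types.

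Peaks of all 6 libraries were merged where they shared 1 bp or more, which gave 231982 regions. A region was called WT-specific or Tet2KO-specific where 3 of 3 libraries of that genotype and 0 of 3 of the other had a peak. On simulated peak sets all 300 and 200 planted regions were found. This checks the counting rule only, and not how often a peak is missed or falsely called. Similarity of peak sets was the base-pair Jaccard index, and reciprocal overlaps were counted with bedtools 2.31.1. Values per library were compared with exact permutation tests over the 10 splits of 6 libraries into 3 and 3, for which the smallest p is 0.1. Shares within a region set carry 95% Wilson intervals, which cover counting error only. Other tests used SciPy 1.17.1 and statsmodels 0.14.6 under Python 3.11.15. Tests across regions treat regions as independent and compare these libraries, not animals.

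Tet2 was named first. Then came the 10 genes with the largest change in each direction among those past the threshold whose groups did not overlap, and of each list the 3 members with the smallest p (5 for the beta cell, ER stress, cell death and interferon lists). Some genes that this rule takes are not reported here. The 5 widest genotype-specific regions and the 5 most changed windows in each direction were named as well. Of the 83 genes named by this rule, 18 overlap another protein-coding gene and share peaks with it, among them Syvn1 (with Mrpl49), Xcr1 (with Fyco1) and Cx3cr1. Genes named outside the rule are said to be so. Alternatives covered the scaling, the pseudocount, the filter, stricter or equal-sized peak lists, counts of peaks, promoter intervals, window sizes, the overlap rule, the set number as a block and leaving out each library. The labels do not tie pools to libraries, and 2 to 3 pools leave open that 2 libraries of a genotype came from the same pool. Here n counts libraries, and p-values measure the spread between libraries, which would then be smaller than that between pools of mice. In genes with few regions whose calls recur, that spread comes from peak edges and scaling, since each peak is a yes or no call. Their limma p can then lie far below 0.1, the smallest exact permutation p for 3 against 3 libraries. Examples are Prf1, Syvn1 and Mcl1, each with 1 WT-specific region of 2.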

Results

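Peak positions and nucleus barcodes were analysed for 6 single-nucleus ATAC-seq libraries of pancreatic islets, 3 from NOD mice (WT) and 3 from Tet2KO NOD mice. The series title names ER stress responses, beta cell death and autoimmunity as the processes of interest, and the comparison asked which genes and cell type markers differed in accessible sequence between the genotypes. The WT libraries held 6317, 5608 and 5701 called nuclei and the Tet2KO libraries 4857, 4590 and 4605. The numbers of peaks used were 171146, 174861 and 173908 in WT and 178915, 159312 and 161041 in Tet2KO.

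Tet2KO libraries held fewer nuclei, with means of 4684 ± 150 (SD, n = 3) against 5875 ± 385 (SD, n = 3) in WT. Every Tet2KO library lay below every WT library, and the exact two-sided permutation p was 0.1. This is the smallest p that 3 against 3 libraries allow. The number of peaks did not separate the genotypes, with 166423 ± 10853 in Tet2KO and 173305 ± 1930 in WT (SD, n = 3, exact permutation p = 0.4). The covered length was 142 ± 9.0 Mb in Tet2KO and 147 ± 1.5 Mb in WT (SD, n = 3, exact permutation p = 0.4). Tet2KO replicate 1 had the most peaks of all 6 libraries.

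Peak sets were more alike within a genotype than between genotypes. The Jaccard index of covered bases averaged 0.745 over 6 pairs within a genotype and 0.660 over 9 pairs between genotypes. The difference of 0.0847 was the largest of the 10 splits of the libraries (exact one-sided permutation p = 0.1, the smallest possible). The pair labelled set 1, WT 1 and Tet2KO 1, had the highest index between genotypes (0.7226), just below the lowest pair within a genotype (0.7232). The closest pairs were WT 2 with WT 3 (0.771) and Tet2KO 2 with Tet2KO 3 (0.768), and the labels leave open whether libraries of a genotype shared a pool of mice. On the first principal component of gene accessibility, which held 47.5% of the variance, WT 1 lay at -11.8 and Tet2KO 1 at 5.66. WT 2 and WT 3 lay at -23.2 and -24.1 and Tet2KO 2 and Tet2KO 3 at 26.9 and 26.6.

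**Figure D1:**
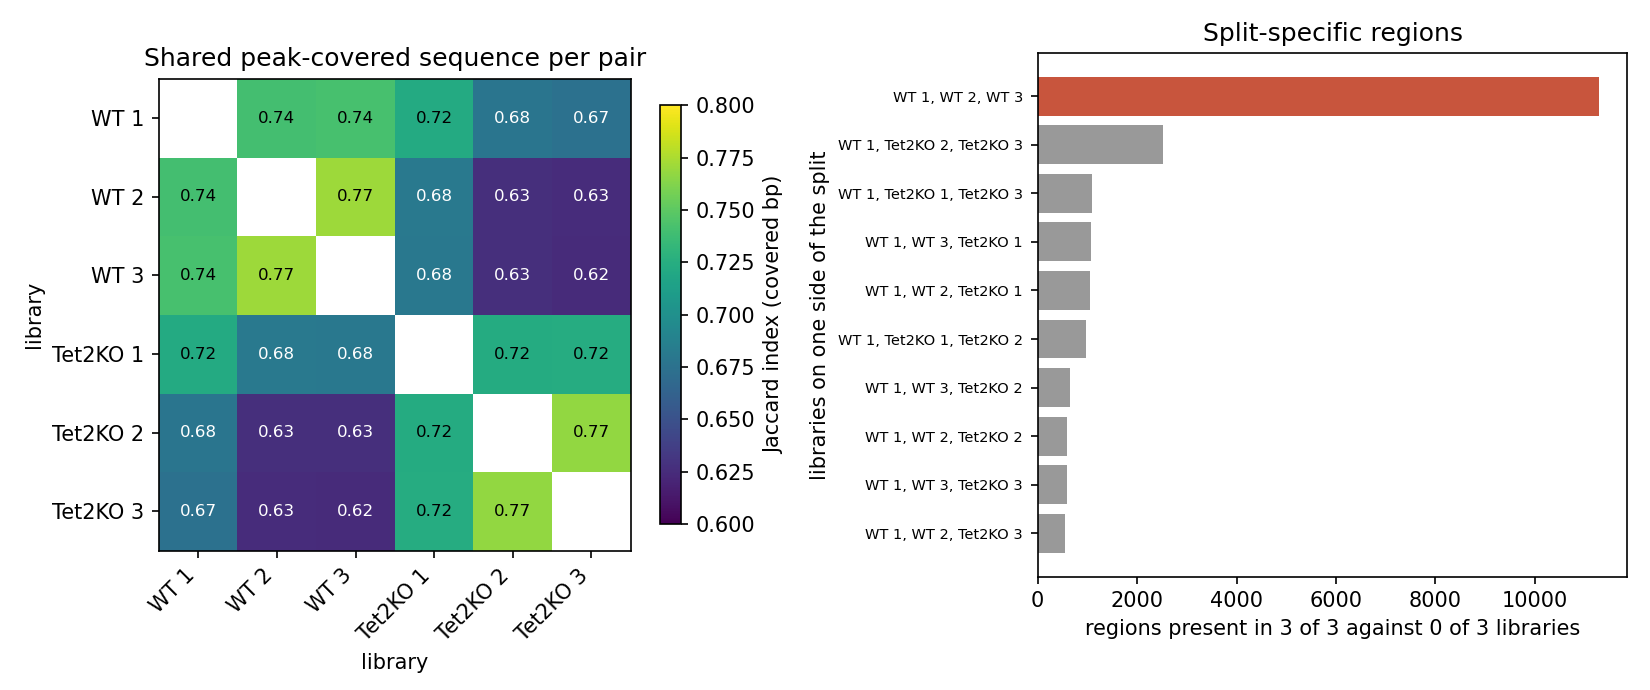
The left panel gives the base-pair Jaccard index of peak-covered sequence for each pair of the 6 libraries, and the right panel the number of regions with a peak in 3 of 3 libraries on one side of a split and 0 of 3 on the other, for the real split (red) and the other 9 (grey). Pairs within a genotype lie between 0.723 and 0.771, and the split by genotype gives 11295 regions against at most 2519 in the others.

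The targeted gene Tet2 (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139, minus strand, GRCm38) had a scaled covered length of 10648 ± 102 bp in Tet2KO and 11885 ± 918 bp in WT (SD, n = 3). Its log2 difference of -0.15 did not pass limma's test (SE 0.070, adjusted p = 0.335). No library had a peak across exons 8 to 10 (133469276 to 133473685), which code for part of the catalytic domain. The peaks in this gene thus did not check the knockout label. In intron 1, a region at 133515002 to 133515862 had a peak in 3 of 3 WT and 0 of 3 Tet2KO libraries. The regions over exon 1 and upstream of it had peaks in all 6 libraries.

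**Figure D2:**
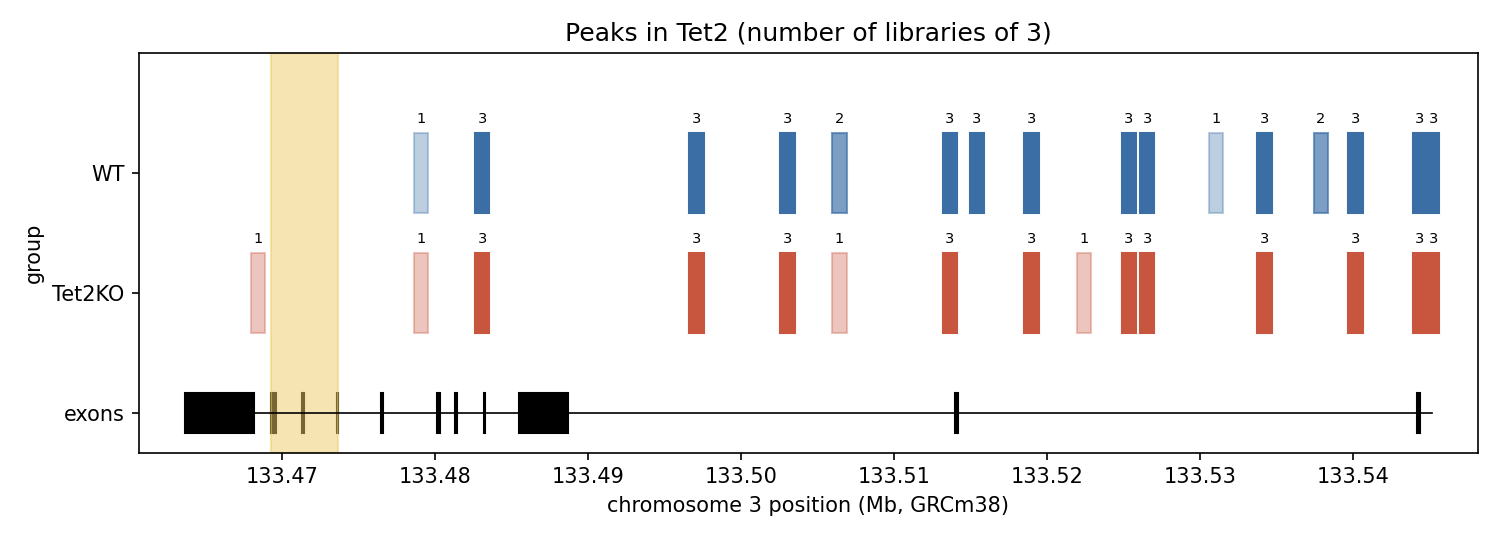
Map of Tet2 on chromosome 3 in Mb, with exons as black boxes, exons 8 to 10 shaded, and regions with peaks drawn for each genotype with the number of libraries of 3 that had the peak. No peak lies in the shaded span in either genotype, and the region at 133515002 is drawn for WT with 3 libraries and is absent from the Tet2KO row.

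Across the genome, 201 genes had more and 341 genes had less covered sequence in Tet2KO than in WT (limma, Benjamini-Hochberg adjusted p under 0.05, 17310 genes tested). Among those with the largest differences, Pirb, an inhibitory receptor of B and myeloid cells, was listed at 0 in all 3 Tet2KO libraries and at 2466 ± 204 bp in WT (SD, n = 3, limma adjusted p = 1.75e-05). Trat1, which codes for a T cell receptor associated transmembrane adaptor, fell from 3412 ± 821 bp to 286 ± 495 bp (SD, n = 3, log2 difference -2.47, SE 0.43, limma adjusted p = 0.0494). Cd200r4 was at 0 against 1514 ± 602 bp (limma adjusted p = 0.0252). Gm9573, Tmem238l, Gml2, Ccdc81 and Ms4a14 were also at 0 in all Tet2KO libraries. Trim40 and Cdhr4 kept at most 356 bp in a Tet2KO library. In the other direction, of the 10 genes named for the largest differences, 9 were at 0 in all WT libraries and above 0 in all Tet2KO libraries. They were Nrk (2749 ± 234 bp), the collagenase gene Mmp13 (1830 ± 105 bp), the aldo-keto reductase gene Akr1c21 (1735 ± 89.0 bp), Fmo6, Mov10l1, Gm17720, Slc17a2, the homeobox gene Dlx5 and the odorant receptor gene Olfr1348 (SD, n = 3). Pcdh12, a protocadherin, rose to 1738 ± 931 bp from 11.9 ± 20.7 bp (SD, n = 3, limma adjusted p = 0.0432). The intervals of Pcdh12 (with Rnf14), Gm9573, Gml2, Cdhr4, Mov10l1, Gm17720 and Olfr1348 overlap other protein-coding genes. Their covered sequence may therefore belong to those genes.

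Of the 542 called genes, 42.8% averaged under 2000 bp (40.2% of tested genes). With a mean of 2000 bp or more required, a limit chosen after seeing the data, 124 were higher and 116 lower. Within 1 kb of the transcription start 166 were higher and 138 lower. Trat1 passed in 6 of 18 alternatives and was lost without scaling (limma adjusted p = 0.0856), with quantile normalization (0.0584), with a pseudocount of 100 bp (0.1001), with equal numbers of peaks (0.0813), with numbers of peaks instead of covered length (0.0552) and within 1 kb of the transcription start (0.552). It was also lost without WT replicate 1 (0.112), 2 (0.230) or 3 (0.240) and without Tet2KO replicate 2 (0.131) or 3 (0.137). With the replicate block only 7 of the 28 named genes past the threshold stayed past it, namely Nrk, Mmp13, Akr1c21, Pirb, Tmem238l, Gml2 and Trim40. All others missed it (limma adjusted p from 0.0804 to 0.218). Among them were Trat1, Cd200r4 and Pcdh12 and, of the genes named below, Themis, Ebf1, Fcer2a, Prf1, Xcr1, Kdr, Syvn1 and Mcl1. Pirb passed in 17 of 17 alternatives, Cd200r4 in 10 of 17 and Pcdh12 in 6 of 16. Pirb was at 0 in every Tet2KO library and alike in the WT libraries, so most alternatives could do little to change its call. Of the 7 genes kept under the block, all but Trim40 were at 0 in every library of 1 genotype. Single libraries moved the counts, to 369 higher and 371 lower genes without WT replicate 1, 142 and 171 without WT replicate 2, and 115 and 155 without WT replicate 3. They were 2430 and 1382 without Tet2KO replicate 1, 91 and 186 without Tet2KO replicate 2, and 84 and 156 without Tet2KO replicate 3. Of the 28 named genes past the threshold, those still past it numbered 17 of 27 that could be tested without WT replicate 1, 11 of 27 without WT replicate 2, and 11 of 28 without WT replicate 3. They numbered 28 of 28 without Tet2KO replicate 1, 14 of 26 without Tet2KO replicate 2 and 9 of 26 without Tet2KO replicate 3, each in the same direction.

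Lymphocyte genes had less covered sequence in Tet2KO islets. All 16 measured genes of the B cell list were lower, with a mean of 5094 ± 355 bp per gene in Tet2KO and 6590 ± 348 bp in WT (SD, n = 3, camera adjusted p = 0.000492). This call was lost with an estimated correlation (adjusted p = 0.579) and under fry (adjusted p = 0.101). Ebf1, a transcription factor of B cell commitment (27622 ± 1646 bp against 37172 ± 401 bp, log2 difference -0.42, SE 0.052, limma adjusted p = 0.0172), passed on its own. Fcer2a, which codes for the low-affinity IgE receptor CD23 (927 ± 45.2 bp against 2239 ± 517 bp, limma adjusted p = 0.0390), passed as well, and Fcrla did not (log2 difference -0.23, limma adjusted p = 0.143). In the T cell list, 18 of 21 genes were lower, with 4527 ± 576 bp per gene against 5912 ± 175 bp (SD, n = 3, camera adjusted p = 0.00265). This call was lost with an estimated correlation (adjusted p = 0.690) and under fry (adjusted p = 0.154). Themis, needed for T cell selection in the thymus, fell from 17345 ± 441 bp to 7158 ± 1665 bp (SD, n = 3, log2 difference -1.24, SE 0.16, limma adjusted p = 0.0193). Themis missed the threshold without WT replicate 2 (adjusted p = 0.0588), WT replicate 3 (0.0691) or Tet2KO replicate 3 (0.0781), and without scaling (0.0514). Ebf1 missed it without WT replicates 2 or 3 (0.0713 and 0.0743) or Tet2KO replicates 2 or 3 (0.0681 and 0.0713), and Fcer2a without the same 4 libraries (0.0950, 0.117, 0.115 and 0.124). Ebf1 (0.0856) and Fcer2a (0.0570) also missed it without scaling, and Fcer2a with quantile normalization (0.0569) and with equal numbers of peaks (0.0566).

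Cd3e and Cd28 had log2 differences of -0.31 and -0.54 that did not pass (limma adjusted p = 0.119 and 0.184). The T cell effector and checkpoint list was lower in 15 of 20 genes (camera adjusted p = 0.0133). Its call was lost with an estimated correlation (adjusted p = 0.690), under fry (adjusted p = 0.154) and with a mean of 2000 bp or more (adjusted p = 0.112). Its perforin gene Prf1 fell from 1659 ± 23.1 bp to 837 ± 53.2 bp (SD, n = 3, limma adjusted p = 0.00511). Of the 2 regions in Prf1, 1 was WT-specific. The granzyme gene Gzma (260 ± 451 bp against 1600 ± 79.7 bp, limma adjusted p = 0.129) and Il2ra (log2 difference -0.36, limma adjusted p = 0.193) did not pass. The macrophage and dendritic cell list missed the threshold (14 of 20 genes lower, camera adjusted p = 0.0564). In it, Xcr1, a chemokine receptor of cross-presenting dendritic cells, passed (log2 difference -0.41, SE 0.069, limma adjusted p = 0.0411). It missed the threshold without WT replicate 1 (0.0819), 2 (0.122) or 3 (0.142) and without Tet2KO replicate 2 (0.125) or 3 (0.0999), with quantile normalization (0.126) and with a mean of 2000 bp or more (0.0692). Cx3cr1 (log2 difference -0.27) and Fcgr1 (log2 difference 0.26) did not.

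Adjusted over the list alone, the passing genes were 2 in the B cell list and 1 each in the other immune lists, the counts that passed over all genes. The macrophage and dendritic cell list passed under fry (adjusted p = 0.0489) but not with an estimated correlation (adjusted p = 0.579). Without Tet2KO replicate 3 the T cell list (adjusted p = 0.0520) and the effector list (adjusted p = 0.125) missed the threshold, as did both within 1 kb of the transcription start (adjusted p = 0.115 and 0.649) and the effector list without scaling (adjusted p = 0.0549). In that interval Themis and Prf1 had log2 differences of 0.01 and 0.05, Fcer2a had one of -0.06 (limma adjusted p = 0.692), and Ebf1 rose (log2 difference 0.30, limma adjusted p = 1.06e-08). Peaks are clipped to a fixed interval there, which can leave replicates almost no spread, so the small p of Ebf1 may overstate the evidence. Every Tet2KO library that was lower in these lists also held fewer nuclei and had peaks at Y-linked promoters that no WT library had.

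**Figure D3:**
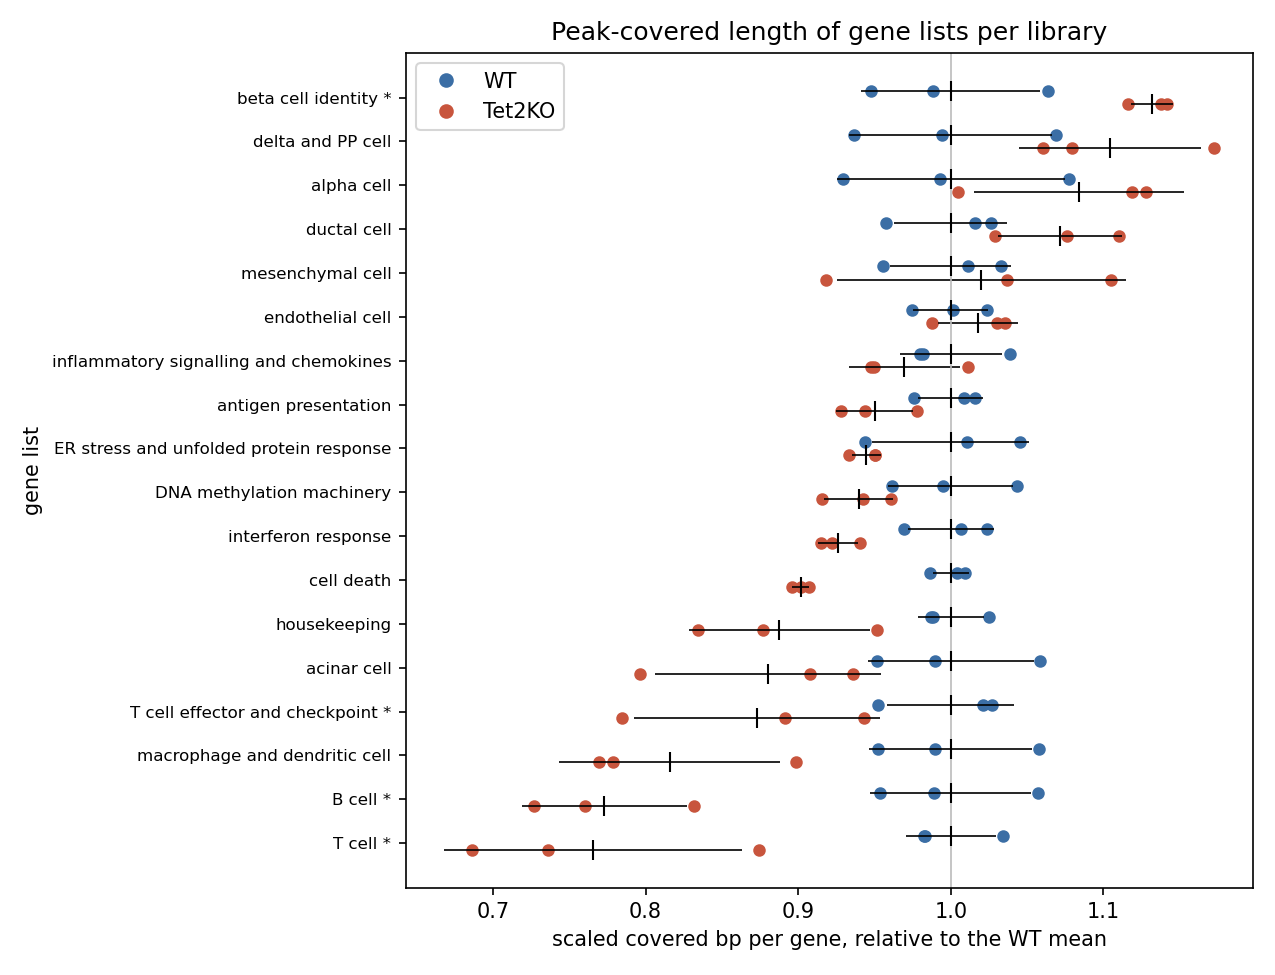
Scaled covered bp per gene of each of the 18 gene lists, divided by the WT mean, with a point per library (WT blue, Tet2KO red), a tick at each mean and a bar of 1 SD (n = 3), and an asterisk where the camera adjusted p was under 0.05. The T cell and B cell lists lie lowest in Tet2KO, at 0.766 and 0.773 of the WT mean, and the beta cell list highest, at 1.13.

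The beta cell identity list had more covered sequence in Tet2KO, in 23 of 25 genes, with 5300 ± 65.2 bp per gene against 4682 ± 275 bp (SD, n = 3, camera adjusted p = 0.0211, adjusted p = 0.690 with an estimated correlation and 0.154 under fry). No gene of it passed, over all genes or adjusted over the list alone. The 5 members with the smallest p were the prohormone convertase gene Pcsk2 (32352 ± 906 bp against 27164 ± 3469 bp, log2 difference 0.25, SE 0.093, limma adjusted p = 0.25) and 4 others that did not pass either. These were Isl1, Nkx2-2 and Pax6, which code for islet transcription factors (log2 differences 0.49, 0.27 and 0.19), and the secretory granule gene Chga (log2 difference 0.61). The alpha cell list (9 of 12 genes higher, among them Gria3 and Loxl4, camera adjusted p = 0.644) did not pass. Neither did the delta and PP cell list (8 of 9 genes higher, among them Lepr, Etv1 and Hhex, camera adjusted p = 0.406). In both lists 0 genes passed over all genes or adjusted over the list alone. The beta cell call was lost without scaling (adjusted p = 0.0716), with quantile normalization (adjusted p = 0.0513), and with equal numbers of peaks (adjusted p = 0.0732). It was also lost within 1 kb of the transcription start (adjusted p = 0.745), and without WT replicate 2 (adjusted p = 0.0978) or Tet2KO replicate 1 (adjusted p = 0.193).

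Of the other cell types of the pancreas, no list passed. In the endothelial list the VEGF receptor gene Kdr rose from 3313 ± 182 bp to 5263 ± 238 bp (SD, n = 3, log2 difference 0.60, SE 0.075, limma adjusted p = 0.0185). This call was lost without WT replicate 2 (0.0717) or 3 (0.0659) or Tet2KO replicate 2 (0.0741) or 3 (0.0818). It was lost as well with equal numbers of peaks (0.0734) and within 1 kb of the transcription start, where the log2 difference was 0.06 (limma adjusted p = 0.692). Robo4 (3214 ± 698 bp against 1144 ± 466 bp, limma adjusted p = 0.0640) and Flt1 (16547 ± 173 bp against 13654 ± 779 bp, limma adjusted p = 0.0821) did not pass over all genes but passed adjusted over the list alone. That gave 3 genes against 1 over all genes. Robo4 also passed over all genes without WT replicate 1 (limma adjusted p = 0.0186), without Tet2KO replicate 1 (0.0350) and without set 1 (0.00286). The list as a whole had 9 of 16 genes higher (camera adjusted p = 0.644). In the mesenchymal list Rgs5 and Lum had log2 differences of 0.46 and 1.45 and Thy1 of -0.30 (camera adjusted p = 0.695). In the ductal list Pkhd1 had a log2 difference of 0.21 and Sox9 of -0.26 (camera adjusted p = 0.695). In the acinar list Zg16, Ctrc and Nr5a2 had log2 differences of -0.43, -0.95 and -0.20 (camera adjusted p = 0.784). The list's median of 0.03 and mean of -0.14 differed in sign. Adjusted over the list alone, 0 genes passed in the mesenchymal, ductal and acinar lists, as over all genes.

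The ER stress and unfolded protein response list did not pass as a group, with 18 of 32 genes higher and 14 lower (camera adjusted p = 0.695). Its median log2 difference of 0.03 and mean of -0.03 differed in sign. Syvn1, an E3 ubiquitin ligase of ER-associated degradation, fell from 1823 ± 72.1 bp to 1049 ± 41.9 bp (SD, n = 3, log2 difference -0.58, SE 0.060, limma adjusted p = 0.00891). Its interval overlaps Mrpl49, and within 1 kb of the transcription start its log2 difference was 0.05, and without Tet2KO replicate 3 the adjusted p was 0.050, just over the threshold. With quantile normalization the call was lost (limma adjusted p = 0.0872). Of the 2 regions in the Syvn1 interval, 1 was WT-specific. The oxidoreductase gene Ero1lb (6771 ± 226 bp against 9388 ± 1016 bp, limma adjusted p = 0.0764), Edem1 and Dnajc3 (log2 differences -0.25 and -0.22) and Herpud1 (log2 difference 0.36) did not pass. Syvn1 was the 1 gene of this list that passed, over all genes and adjusted over the list alone.

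In the cell death list 15 of 27 genes were lower and the list missed the threshold (camera adjusted p = 0.0739), with 4564 ± 28.2 bp per gene in Tet2KO and 5061 ± 60.6 bp in WT (SD, n = 3). Mcl1, an anti-apoptotic BCL2 family member, fell from 1458 ± 14.0 bp to 869 ± 53.9 bp (SD, n = 3, log2 difference -0.52, SE 0.048, limma adjusted p = 0.00560). It was the 1 gene that passed, also adjusted over the list alone, and 1 of its 2 regions was WT-specific. With equal numbers of peaks its log2 difference was -0.02 and the call was lost (limma adjusted p = 0.357). The anti-apoptotic genes Bcl2l1 and Bcl2 (log2 differences -0.22 and -0.21), the death receptor gene Fas (log2 difference -0.37) and Casp9 (log2 difference -0.59), which shares peaks with Ctrc, did not pass.

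The interferon response list did not pass (17 genes higher and 16 lower, median log2 difference 0.01 and mean -0.10, camera adjusted p = 0.644). Log2 differences were -0.29 for Stat2, -0.40 for Cd274, -0.42 for Ciita, -0.53 for Gbp3 and 0.65 for Iigp1. In it 0 genes passed over all genes or adjusted over the list alone. In the antigen presentation list (camera adjusted p = 0.644) the peptide transporter gene Tap2 (3261 ± 442 bp against 4826 ± 45.3 bp, limma adjusted p = 0.0668) passed adjusted over the list alone (1 gene against 0 over all genes). Within 1 kb of the transcription start Tap2 passed over all genes (log2 difference -0.70, limma adjusted p = 2.91e-44), and this list passed as lower (camera adjusted p = 0.00264). Peaks are clipped to a fixed interval there, which can leave replicates almost no spread. So small a p from 6 libraries is not a measure of the strength of the evidence. Tap1 and H2-Aa had log2 differences of -0.41 and -0.39. In the inflammatory signalling list (median log2 difference 0.03 and mean -0.02, camera adjusted p = 0.969) Il1b, Nos2 and Nfkbia had log2 differences of -0.42, 0.29 and -0.12. In the DNA methylation list (camera adjusted p = 0.315) Tdg, Dnmt1 and Apobec1 had log2 differences of -0.51, -0.34 and -0.38. In the housekeeping list (camera adjusted p = 0.695) the X-linked genes Hprt and Pgk1 had log2 differences of -0.38 and -0.998 and Polr2a of 0.14. Of the inflammatory, DNA methylation and housekeeping lists, 0 genes passed over all genes or adjusted over the list alone.

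A total of 6351 regions had peaks in all WT and no Tet2KO libraries (2.74% of 231982), and 4944 in all Tet2KO and no WT libraries (2.13%). Of the rest, 117401 regions were present in all 6 libraries. The T cell list held 17 WT-specific regions among 174 regions, 9.77% against 2.65% of other genic regions (Fisher's exact test over regions, two-sided, odds ratio 3.98, p = 4.72e-06, adjusted p = 0.000170). In Themis lay 9 of these 17. The B cell list held 12 among 163 (odds ratio 2.92, adjusted p = 0.0266), with 7 in Ebf1 and 1 each in Cd79a, Blk, Cd22, Bank1 and Pou2af1. The effector list held 6 among 170 (odds ratio 1.34, adjusted p = 1) and the macrophage and dendritic cell list 3 among 156, fewer than other genic regions (odds ratio 0.718, adjusted p = 1). Without Tet2KO replicate 1 the T cell, B cell, effector and macrophage and dendritic cell lists held 33, 22, 21 and 24 WT-specific regions. All WT-specific regions then numbered 14755. Without WT replicate 1 the same lists held 23, 22, 13 and 11, and all WT-specific regions numbered 12033. The low macrophage and dendritic cell count thus depended on Tet2KO replicate 1. Without Themis the T cell list held 8 among 153 (odds ratio 2.02, Fisher's exact p = 0.0688). The beta cell list held 0 WT-specific and 4 Tet2KO-specific regions among 203, with regions in Nkx2-2, Pcsk2 and Sytl4 among the latter (Fisher's exact adjusted p = 0.0899 and 1). Genes outside the fixed rule, named here after their counts were seen, were Cd79a, Blk, Cd22, Bank1, Pou2af1, Sytl4, and Adgrl3, Dab1 and Ntm with 8 Tet2KO-specific and 0 WT-specific regions each (Fisher's exact adjusted p = 0.0489).

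The widest WT-specific regions lay in an exon of Lrrc58 (chromosome 16, 37876078 to 37877920), an exon of Zrsr2 (X, 163950626 to 163952228), between genes (19, 16949868 to 16951448), in an intron of Slc9a7 (X, 20286126 to 20287586) and in an intron of Ptk2b (14, 66248840 to 66250332). The widest Tet2KO-specific regions lay in introns of Nalcn (14, 123565769 to 123567452) and Meiob (17, 24820884 to 24822524) and between genes (8, 8575908 to 8577980; 5, 77865089 to 77866801; 12, 104636946 to 104638624). Promoters, within 1 kb of a transcription start, made up 3.12% of WT-specific regions (95% Wilson interval 2.72 to 3.57) and 2.51% of Tet2KO-specific regions (2.11 to 2.98), against 12.7% of regions present in all 6 libraries (12.5 to 12.9). Exonic regions made up 13.1% of the WT-specific (12.3 to 13.9) and 7.36% of the Tet2KO-specific regions (6.67 to 8.12). The counts went to 12033 WT-specific and 8681 Tet2KO-specific regions without WT replicate 1, and to 14755 and 7510 without Tet2KO replicate 1. Leaving out another library gave 7151 to 7906 WT-specific and 6041 to 7050 Tet2KO-specific regions.

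Of 21157 windows of 100 kb, 958 had more and 517 less covered sequence in Tet2KO (limma, adjusted p under 0.05). The window with the natural killer cell receptor gene Ncr1 and the platelet collagen receptor gene Gp6 (chromosome 7, 4300001 to 4400000) held 3335 bp in WT and 0 in Tet2KO (limma adjusted p = 0.00786). The others of the 5 lowest lay on chromosome 17 (40200001 to 40300000, with Pgk2, Crisp3 and Crisp1) and chromosome 14 (18400001 to 18500000). They also lay on chromosome 16 (18900001 to 19000000, with Gm28539 and Hira) and chromosome 8 (127600001 to 127700000, with Pard3). The 5 most raised were at 0 in WT and lay in Nrg3, which codes for a neuregulin (chromosome 14, 38700001 to 38800000, 4044 bp in Tet2KO, limma adjusted p = 0.00987) and on chromosome 12 (95500001 to 95600000). The others lay on chromosome 11 (48200001 to 48300000), at 6030498E09Rik (X, 38700001 to 38800000) and in Ranbp17 (chromosome 11, 33400001 to 33500000). Single libraries moved these counts to 1694 higher without WT replicate 1, 129 lower without WT replicate 2, and 126 lower without WT replicate 3. They went to 940 lower without Tet2KO replicate 1, 112 higher and 21 lower without Tet2KO replicate 2, and 115 higher and 17 lower without Tet2KO replicate 3. In turn, quantile normalization gave 218 higher and 191 lower and no scaling 327 lower.

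Promoter peaks were present at 100% of B cell list genes in each WT library and at 91.7% ± 3.6 in Tet2KO (SD, n = 3, exact permutation p = 0.1, the smallest possible, adjusted p = 1 over 18 lists). In the T cell list the shares were 98.4% ± 2.7 in WT and 90.5% ± 9.5 in Tet2KO (SD, n = 3, exact permutation p = 0.4). The beta cell list stood at 92% in WT and 93.3% ± 2.3 in Tet2KO, and the cell death list at 92.6% in every library. Over all protein-coding genes the shares were 70.1% ± 0.045 in WT and 69.7% ± 0.67 in Tet2KO (SD, n = 3, exact permutation p = 0.4).

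The region around Tet2 was examined because the allele came from a B6 background. Within 10 Mb of Tet2, 28 of 1700 regions were Tet2KO-specific, an odds ratio of 0.768 against the rest of the genome (95% interval 0.508 to 1.12, Fisher's exact p = 0.178). In the same interval 59 were WT-specific (odds ratio 1.28, Fisher's exact p = 0.0727), and within 5 Mb the odds ratio of WT-specific regions was 1.43 (Fisher's exact p = 0.0330). Other splits of the libraries reached 2.82 within 5 Mb. On the whole of chromosome 3 the odds ratio of Tet2KO-specific regions was 1.11 (Fisher's exact p = 0.0856). Pairs of libraries shared between 27 and 48 barcodes, close to the 29.3 to 49.9 given by chance from a pool estimated from the same pairs. At most 0.107% of peaks had identical coordinates in a pair.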

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

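The tests of antigen receptor loci, of numbers of nuclei and peaks, of sex, of the Y-linked promoters and their X copies, of WT-specific regions near Tet2 and on chromosome 3 and of the lists under other splits were chosen after the results were seen. Peaks at the promoters of 4 Y-linked genes, Kdm5d, Eif2s3y, Uty and Ddx3y, were present in all 3 Tet2KO and in 0 of 3 WT libraries, and drew attention because these genes fell outside the gene test. Reads of X-Y shared sequence placed on Y are argued against as the whole cause at these 4 promoters. The promoters of all 4 X copies, Kdm5c, Eif2s3x, Kdm6a and Ddx3x, had a peak in every WT library, where those of the Y copies had none. Elsewhere on Y the WT libraries did have peaks (16, 14 and 14), and 12 of 27 Y regions were present in all 6 libraries. Nuclei from male mice in the Tet2KO pools stay open, since the test used for them, that these 4 Y-linked promoters carry peaks, restates the observation. These peaks and the genotype coincided in all 6 libraries, so sex cannot be told apart from genotype in any comparison here. At the start site of Xist, which is transcribed from the inactive X, the peak was present in 3 WT libraries and in Tet2KO 1 and absent from Tet2KO 2 and Tet2KO 3, and the labels name female NOD mice and bone marrow donors without tying either to the islet libraries.

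The T cell and B cell lists were lower and the beta cell list higher in Tet2KO. Fewer nuclei and peaks in the Tet2KO libraries stay open for the beta cell list, which without scaling stood at 1.09 times WT but separated the groups narrowly (lowest 5014.5 against highest 5010.9 bp), and whose camera call was lost without scaling (adjusted p = 0.0716), with equal numbers of peaks (0.0732) and with an estimated correlation (0.690). For the immune lists, fewer peaks are argued against as the whole cause, since both lists passed with equal numbers of peaks (camera adjusted p = 0.0212) and without scaling lay lower in every Tet2KO library, although an estimated correlation ended both calls (T cell 0.690, B cell 0.579), but fewer nuclei cannot be told apart from genotype, since 0 Tet2KO libraries had as many nuclei as a WT library. A smaller share of immune nuclei may account for the lower immune lists: covered length in the antigen receptor loci, which no list holds, was 0.623 of WT (exact permutation p = 0.1, the smallest possible), lower in every Tet2KO library, although the T cell receptor alpha locus alone did not separate the groups (ratio 0.935). Different sex of the mice cannot be told apart from genotype either, since 0 libraries had Y-linked promoter peaks that parted from their genotype, and less accessible chromatin within immune nuclei stays open and untested, as no values per nucleus were used.

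The regions with peaks in all libraries of one genotype and none of the other were weighed against B6-derived DNA linked to the Tet2 allele. For either set as a whole it is argued against: chromosome 3 held 5.53% of the WT-specific and 5.95% of the Tet2KO-specific regions, near the 5.39% of all regions, and the odds ratio of Tet2KO-specific regions within 10 Mb of Tet2 was 0.768. For the 59 WT-specific regions near Tet2 it stays open, with an odds ratio of 1.28 within 10 Mb (Fisher's exact p = 0.0727) and 1.43 within 5 Mb (0.0330). The highest in the other splits were 2.04 for 10 Mb and 2.82 for 5 Mb. Base composition differed, with 45.3% GC in WT-specific and 43.0% in Tet2KO-specific regions, but 13 of 16 sequence motifs still differed within strata of GC content. A difference in the cell types sampled and the genotype itself both stay open.

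With 10 splits of the 6 libraries, no share under 0.05 is possible. The split by genotype gave the largest result in 1 of 10 splits for each count: 11295 regions against at most 2519 in another split, 542 genes against at most 48, 1475 windows against 0, and 4 gene lists against at most 3. The split of WT 1, Tet2KO 2 and Tet2KO 3 against the rest gave the 2519 regions and the 48 genes.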

How the results depend on the processing

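The alternatives without set 1, with autosomes only and with a mean of 2000 bp or more were chosen after seeing the data; the cause of each change below was not tested unless the setting itself shows it. Deviations of libraries with the same set number correlated at -0.065, -0.025 and -0.015, which gave no sign of pairing over all genes. A shift of set 1 towards the other genotype in both groups would not raise this correlation, so a shared effect of set 1 is not excluded. On the second principal component (15.4% of the variance) WT 1 and Tet2KO 1 lay at 11.3 and 21.4. The other libraries lay between -10.9 and -4.21. With the replicate block, 3 genes were higher and 9 lower, and 63 windows higher and 5 lower, with fewer residual degrees of freedom; the block kept the calls of the beta cell, T cell, effector and B cell lists and added the macrophage and dendritic cell list (adjusted p = 0.0288). Without scaling 327 windows were lower and 0 lists higher. Quantile normalization gave 218 windows higher, 191 lower and 0 lists higher, and equal numbers of peaks 0 lists higher. Within 1 kb of the transcription start 166 genes were higher and 138 lower and 0 lists were higher, the antigen presentation list gained a call (lower, adjusted p = 0.00264), and Themis (0.0142), Prf1 (0.0481), Syvn1 (0.0513) and Ebf1 (0.30) turned to positive log2 differences. An estimated correlation left 0 lists higher and 0 lower, and fry 0 higher and 1 lower. That 1 was the macrophage and dendritic cell list (adjusted p = 0.0489), and the B cell (0.101), T cell, effector and beta cell lists (0.154 each) were lost under fry. Windows of 20 kb gave 1171 lower. A mean of 2000 bp or more gave 124 genes higher and 116 lower, from fewer genes. Without set 1, 2854 genes were higher and 1571 lower, 0 lists were higher, and 22346 WT-specific and 11857 Tet2KO-specific regions were found. Leaving out 1 library gave 84 to 2430 genes higher and 155 to 1382 lower, 112 to 1694 windows higher and 17 to 940 lower, 0 to 1 lists higher and 1 to 3 lower, 7151 to 14755 WT-specific regions (at most 7906 with both set 1 libraries kept) and 6041 to 8681 Tet2KO-specific regions. The B cell list passed in 19 of 21 alternatives, the T cell list in 17, the effector list in 15 and the beta cell list in 12, each in the same direction in all 21. All alternatives but the estimated correlation and fry kept the preset correlation of 0.01. The estimates were 0.144 for the B cell, 0.229 for the T cell, 0.240 for the effector and 0.140 for the beta cell list. Each of these calls was lost under both settings without the preset, so the tallies do not show that the calls hold without it. Peak set similarity kept its direction under its 11 alternatives, but no p under 0.05 is possible in this design. The odds ratio of Tet2KO-specific regions near Tet2 lay between 0.598 and 0.996 under its 11 alternatives and passed no threshold. Median differences of all genes moved from 0.03 to -0.01 without scaling. The depth behind each peak call is unknown, which limits what a missing peak shows.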

Other observations

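The tests of the antigen receptor loci, of region counts per gene and without set 1 were chosen only after results had been seen, and the motifs were chosen after the gene lists had been tested but before any sequence was read. Sequence motifs separated the 2 sets of genotype-specific regions. The PU.1 motif, bound by a myeloid and B cell factor, occurred in 14.0% of WT-specific and 5.12% of Tet2KO-specific regions (odds ratio within GC strata 2.92, adjusted p = 3.67e-47), and the ETS motif in 25.5% and 12.9%. NF-kB (13.2% and 6.05%), AP-1 (25.1% and 14.6%), RUNX (16.5% and 10.6%) and IRF motifs (15.7% and 13.1%) were also more frequent in WT-specific regions. The TCF/LEF motif (18.3% and 17.4%) passed only within GC strata (adjusted p = 0.0182, against 0.231 without strata). Tet2KO-specific regions held more HNF1 (2.27% against 0.677%), FOXA (16.2% against 9.21%), RFX (2.02% against 1.4%), homeobox (10.9% against 6.74%), MAF (12.8% against 10.8%) and NEUROD motifs (12.2% against 10.5%) than WT-specific regions. These motifs are bound by factors used in endocrine and other pancreatic cells among other tissues. In 10000 sampled shared regions NEUROD stood at 12.85%, above both sets, so it was not enriched in Tet2KO-specific over shared regions. HNF1, FOXA, RFX, homeobox and MAF were more frequent in Tet2KO-specific than in shared regions. NF-kB stood at 11.1% in shared regions, between the sets. EBF, GATA and CTCF motifs did not differ within GC strata. Regions, not animals, are the units of these p-values.

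The antigen receptor loci, which lie outside the lists, had less covered sequence in Tet2KO for Igh (37954 ± 17710 bp against 79496 ± 8943 bp, SD, n = 3), Igk (21264 ± 1181 bp against 39905 ± 7863 bp), Igl, Trb (19278 ± 6829 bp against 32083 ± 2820 bp) and Trg, each with every Tet2KO library below every WT library (exact permutation p = 0.1, the smallest possible). The Tra locus, which holds Trd, was at 49590 ± 3590 bp against 53031 ± 5405 bp (exact permutation p = 0.6). Of 6 loci, 5 thus separated the groups. The chance share of 10% holds for 3 against 3 libraries that do not differ by group. These libraries parted by genotype across the genome, with a limma p under 0.05 for 3081 of 17310 tested genes. The share of other loci that separate the groups was not counted, and the 6 loci were not shown to be independent. The count of 5 was therefore not tested against a background.

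Of the genes with genotype-specific regions, 17 held 5 or more Tet2KO-specific and 0 WT-specific regions, with a median length of 968 kb, among them Dlg2 and Ptprd. Fisher's exact test passed for genes that included Adgrl3, Dab1 and Ntm (adjusted p = 0.0489 each), all chosen after their counts were seen. In the other direction 7 genes held 5 or more WT-specific and 0 Tet2KO-specific regions, with a median length of 472 kb, among them Themis and Fars2 with 9 each. Longer genes hold more regions of any kind, and a relation to gene length was not tested. The X chromosome held 171 Tet2KO-specific and 138 WT-specific regions, 3.07% and 2.48% of its regions, against 2.13% and 2.74% of all regions. The share of peaks on X was 2.41% ± 0.046 in Tet2KO and 2.27% ± 0.025 in WT (SD, n = 3, exact permutation p = 0.1, the smallest possible). Of its 582 tested genes, 9 were higher, among them Nrk, and 12 lower in Tet2KO, against 201 and 341 of all 17310 tested genes. Chromosome Y held 5 Tet2KO-specific and 0 WT-specific regions.

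Set 1 stands between the genotypes in both groups. The labels give 3 min of lysis for 2 libraries and 5 min for 4, without tying them to sets, so this was not tested. Without set 1 of both genotypes, 2854 genes were higher and 1571 lower in Tet2KO.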
